A study of Mus musculus with 4 samples.

How the data were processed

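Single-cell RNA was measured in whole mouse pancreas with the 10x Genomics platform. There were 4 libraries, 1 in each of the groups NFD, AP, HFD and HAP. The deposited matrices hold counts, whole numbers of unique molecular identifiers (UMIs) per gene and barcode, without filtering or normalization by the authors. Each matrix lists 32285 genes and 6794880 barcodes, so that empty droplets are included and no calling of cells had been applied. Per the labels the reads were aligned to mm10 with Cell Ranger 2.1.1, while the matrix headers name Cell Ranger 4. The reason for that difference is not given in the sources used here. The cell preparation text of the labels describes sorted gut goblet cells, which does not match pancreas, so nothing was taken from it. Positions are from GENCODE vM21 on the same mm10 build, and 32158 of the 32285 gene identifiers (99.6%) matched it.

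A barcode was kept as a cell with at least 200 genes and at most 20% of its UMIs from mitochondrial genes. The minimum of UMIs started at 500 and was raised for every library alike, in steps of 250, until no library kept more than 15000 barcodes. This gave a minimum of 3000 UMIs. Doublets were scored per library with Scrublet, as built into scanpy 1.11.5. Its automatic threshold marked 0 of the NFD barcodes, 56 of AP, 7 of HFD and 6 of HAP and was taken as not working. The barcodes with the highest scores were removed instead, at a rate of 0.8% per 1000 barcodes, which took out 1476, 267, 15 and 172. That departure from the plan was chosen after the data were examined.

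The kept cells of the 4 libraries were clustered together. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen, and 30 principal components and 15 neighbours were used. Clusters were drawn with leidenalg 0.10.2 at resolution 1 and seed 1, without batch correction, since library and group are the same. The neighbour graph was weighted by shared neighbours. A marker counted as raised when it was found in at least 10% of the cells of a cluster and lay at least 1 log2 unit above the mean of the other clusters, with 10 CPM added. A class needed 3 raised markers. Among such classes the name went to the one with the most markers among the 10 leading genes of the cluster and, where these numbers were equal, to the one with the larger share of its markers raised. Acinar was given where its markers led or no other class had 3 raised. Of the named clusters, 9 had no marker of their class among the leading genes, so that raised markers alone named them. A cluster with raised markers of both immune and other classes in like number, or led by genes of another class, stayed unnamed. The 23 marker lists were fixed before the data were examined, and this rule for naming was set afterwards. All 37 clusters were named, and 28 of them held over 90% of their cells from 1 library, so that cells compared within a class mostly came from different clusters. Class names carry the ending "-like" because they rest on RNA markers alone.

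Counts were summed per library and class and scaled to CPM, counts per 1000000 UMIs of the class total. Mitochondrial genes were left out of that total, and outside acinar-like cells the acinar secretory genes were left out too. Genes with at least 20 UMIs over the 2 libraries compared were measured. A class was compared where both libraries had at least 50 cells. With 1 library per group no test between groups was possible, and no p-values or counts of changed genes are given. Shares have exact Clopper-Pearson 95% intervals, summed counts exact Poisson 95% intervals, and ratios of CPM exact conditional binomial 95% intervals. Intervals of share ratios run between opposite ends of the 2 share intervals, and those of differences between such ratios join opposite ends again. They are wider than 95% intervals, so one that spans 0 does not place a difference within counting error. All of these cover counting error only and not the variation between mice. Where a count was 0, the ratio was taken against a floor of 3 counts and is given as at least or at most.

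Each of 21 gene lists was summarised by the median log2 ratio of CPM over its measured members. Its interval came from 1000 Poisson redraws of the counts. Its standing was the percentile of that median among 10000 random lists of equal size, matched on mean expression over 20 bins. The libraries differed in composition, so the median over all genes was not 0. It was 0.41 in fibroblast-like, 0.46 in macrophage-like, 2.15 in acinar-like and 0.73 in neutrophil-like cells for AP against NFD. For HFD against NFD it was 0.31 in fibroblast-like, 0.10 in acinar-like and 0.31 in macrophage-like cells. For HAP against HFD it was 0.19 in fibroblast-like cells. For HAP against AP it was -0.06 in fibroblast-like, -1.15 in neutrophil-like and -0.37 in mesothelial-like cells. The percentiles set each list against this shift, but not against how its members vary together. TMM factors took out much the same shift, 2.14 in acinar-like and 0.88 in neutrophil-like cells for AP against NFD and -1.15 in neutrophil-like cells for HAP against AP. Random lists were matched on size and mean expression only. A percentile, also one above or below all random lists, is therefore a description and not a test. Lists outside percentiles 2.5 to 97.5 were common. For AP against NFD, 8 lists lay outside and 1 within in fibroblast-like cells. In neutrophil-like cells 2 lay outside and 5 within.

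The comparisons were AP against NFD, HFD against NFD, HAP against HFD and HAP against AP, together with the difference between diets in the pancreatitis ratio of the immune share. Named genes followed a rule set before the data were examined. In each comparison and in up to 4 classes with the most cells, and in acinar-like cells, the 3 highest and 3 lowest ratios were taken by the bound of the interval nearest to 1. Mitochondrial, ribosomal, haemoglobin, antigen receptor, sex-linked and unnamed gene models were left out, as were markers of another class. Outside acinar-like cells the acinar secretory and regenerating protein lists were left out of that ranking. From each list 2 to 4 members with the largest ratios were taken. Genes named by other reasons are stated as such.

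The gene lists, the filters and the intervals were fixed before the data were examined. So were alternatives for the immune share, the acinar secretory list in acinar-like cells and the inflammatory list in macrophage-like cells, each for those of them it bears on. They were a minimum of 6000 UMIs, at most 10% mitochondrial UMIs, doublets kept, resolutions of 0.5 and 2, classes assigned cell by cell, cells thinned to 500 UMIs, CPM over all genes, TMM factors from edgeR 4.0.16, no count minimum with 0.5 UMIs added, and, for the inflammatory list, subtraction of free RNA. Free RNA is RNA outside cells that enters every droplet. Its profile came from barcodes with 10 to 100 UMIs of the same library. Alternatives added after the data were examined were a minimum of 10000 UMIs in NFD alone, a minimum of 1000 UMIs in AP, HFD and HAP, doublets by the automatic threshold, CPM without 3 genes that overlap ribosomal RNA or the like, a free RNA profile from barcodes with 250 to 2000 UMIs, free RNA subtraction in other lists, and leaving acinar-like cells out of the denominator of the immune share. For the other lists and the named genes every alternative was added after the data were examined. Free RNA was scaled by the acinar secretory share of a class, which put it at 100% of acinar-like RNA by construction. In macrophage-like cells of AP and HFD and fibroblast-like cells of AP and HAP, this scaling would give more S100a9 than was counted. It overstates free RNA there, so its subtraction may take cell RNA too.

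The intervals and percentiles were tested on simulated data, in which counts were drawn from the pooled profile of a pair of libraries and 200 genes were changed, in 20 runs for each of 4 pairs. Percentiles of lists whose unchanged members vary together were not tested by these draws. The intervals held the true ratio for 95.7% to 96.8% of genes. Of genes changed 2-fold, 75.2% to 90.8% had an interval on the right side of 0, and of those changed 4-fold, 96.0% to 99.6%. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3. Mice given astragalus polysaccharides, which the series text names, were not analysed here.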

Results

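Gene expression was measured cell by cell in the pancreas of C57BL/6J mice in 4 groups, with 1 library each and no replicates. AP and HAP mice received 12 hourly injections of caerulein at 50 µg/kg, a cholecystokinin analogue that overstimulates acinar cells and causes acute pancreatitis. AP mice were on the normal diet and HAP mice on a high-fat diet, and HFD mice had the high-fat diet without caerulein. Diets lasted 12 weeks. The library titled NFD was taken as the normal control group. The number of mice behind each library is not given in the sources used here.

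The libraries held 223079841 UMIs in NFD, 140806310 in AP, 50220285 in HFD and 65383591 in HAP. At a shared minimum of 3000 UMIs, 12209 cells were kept in NFD, 5514 in AP, 1522 in HFD and 4535 in HAP. Of those of NFD, 10827 were acinar-like barcodes, for which droplets without a cell stay open. Shares and ratios over all cells that involve NFD rest on that uncertain count. Depth differed between them, with a median of 4373 UMIs and 376 genes per cell in NFD, 13100 and 3467 in AP, 8511 and 2298.5 in HFD, and 5868 and 1461 in HAP. Among barcodes with at least 100 UMIs, the fullest bin of NFD was that of 2000 to 3000 UMIs (29984 barcodes, with a median of 222 genes), whereas in the other libraries it was that of 250 to 500 UMIs. Mitochondrial RNA took 0.332% of all UMIs in NFD, 5.11% in AP, 20.1% in HFD and 2.30% in HAP. Gm42418, a gene model that overlaps ribosomal RNA, took 17.4%, 12.5%, 23.8% and 4.05%. Y-linked RNA was counted in every library (1257, 17266, 2186 and 5612 UMIs in kept cells) and Xist hardly at all (0, 10, 3 and 5 UMIs), the pattern of male animals.

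**Figure D1:**
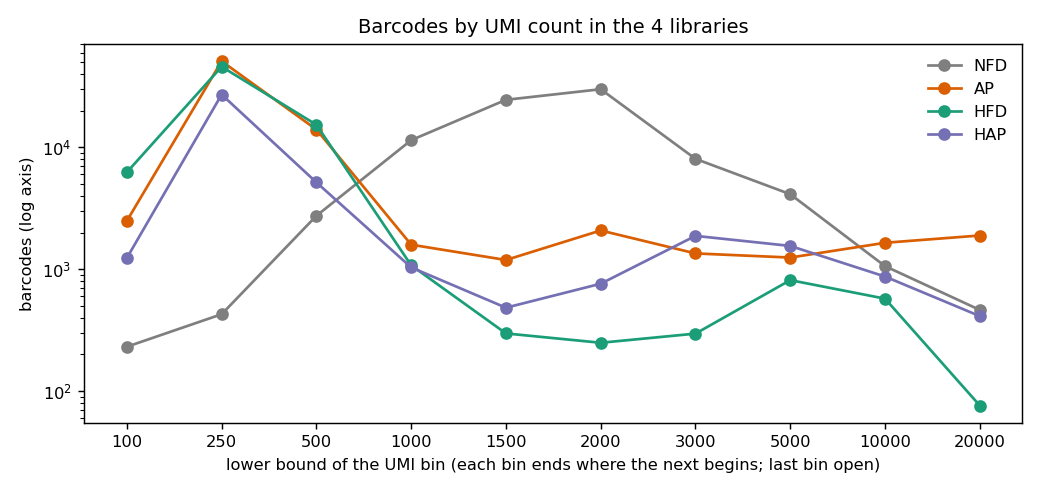
Number of barcodes with at least 100 UMIs (log axis) by the lower bound of their UMI bin in the 4 libraries, with the last bin open above 20000 UMIs. In this range the NFD line peaks at 29984 barcodes with 2000 to 3000 UMIs, while AP, HFD and HAP peak in the bin from 250 UMIs.

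The comparison of AP with NFD asks how pancreas with caerulein pancreatitis differed on the normal diet. Immune-like cells made up 49.5% of AP cells (95% interval 48.2 to 50.9) and 3.24% of NFD cells (2.94 to 3.57), a log2 ratio of 3.93 (3.75 to 4.11). Acinar-like barcodes, which carry the digestive enzymes, were 88.7% of NFD cells (10827) and 2.88% of AP cells (159). Among cells that were not acinar-like, a denominator chosen after the data were examined, immune-like cells were 51.0% in AP and 28.7% in NFD, a log2 ratio of 0.83 (0.67 to 0.99). The makeup of the immune-like cells differed. Dendritic-like cells, which present antigen to T cells, were 22.9% of them in AP and 1.26% in NFD (5 cells). Macrophage-like cells were 40.8% in AP and 72.0% in NFD, neutrophil-like cells 17.9% and 14.4%, T-like cells 4.80% and 4.55%, and NK-like cells 7.32% and 5.30%. These shares depended on the settings. Neutrophil-like cells were 42.2% of the immune-like cells of AP with a minimum of 1000 UMIs in AP, HFD and HAP, and 0.971% in AP and 0.690% in NFD with a minimum of 6000 UMIs. At resolution 0.5 AP had 125 macrophage-like and 1224 monocyte-like cells. Among cells that were not acinar-like, endothelial-like cells were 0.0187% in AP (1 cell) and 13.5% in NFD (186 cells).

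**Figure D2:**
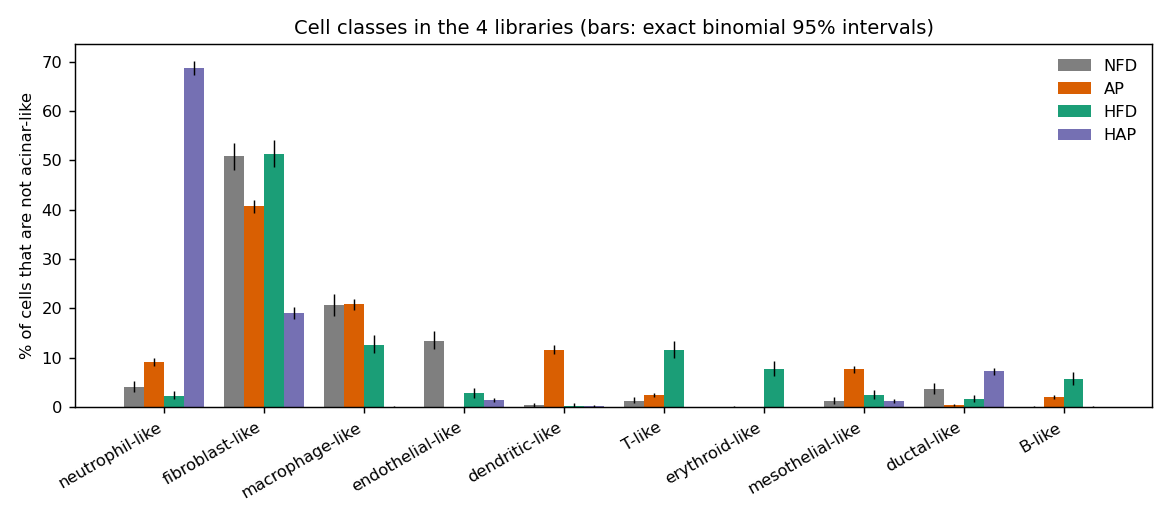
Share of each cell class among cells that were not acinar-like (vertical axis, percent) in the 4 libraries, with exact binomial 95% intervals as bars. Neutrophil-like cells stand at 68.7% in HAP against 9.11% in AP, 4.12% in NFD and 2.31% in HFD.

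Fibroblast-like cells of AP (2178) carried far more RNA of inflammation, matrix and cell division than those of NFD (702). Each library had its own main fibroblast-like cluster (98.9% of these cells in NFD, 79.6% in AP, 98.5% in HFD and 100% in HAP), so that state, subtype and library were not told apart in any of the comparisons. The inflammatory cytokine and chemokine list had all 21 measured members higher in AP, with a median log2 ratio of 3.06 (95% interval 2.53 to 3.19), above all 10000 random lists. Its largest ratios were Cxcl5, which attracts neutrophils (4.94, interval 4.19 to 5.81), Osm (4.89, 2.41 to 10.20), Il1b (4.89, 4.11 to 5.80) and Ccl4 (4.57, 3.02 to 6.85). Neutrophil RNA was higher in the same cells, since S100a9 stood at 147 CPM in AP and 2.65 CPM in NFD. With free RNA subtracted the list median was 1.81, and Ccl4 had 0 UMIs left in both libraries. Il1b was 102 CPM in these cells of AP. Free RNA, put at 11.7% of their RNA, held 839 CPM of Il1b, so by this scaling most of it would be free RNA. The same scaling would give more S100a9 than the 147 CPM counted, so it overstates free RNA there. The list of extracellular matrix and fibroblast activation had 15 of 18 members higher, with a median of 1.83 (1.78 to 1.84). The matrix protein Tnc reached 7.49 (6.13 to 9.37), and the contractile genes Acta2 6.52 and Tagln 3.55, whereas the acute-phase gene Saa3 lay at -4.33. All 14 members of the proliferation list were higher, with a median of 3.48 (3.12 to 3.88), led by Ube2c at 6.18, Ccnb1 at 6.03 and Ccnb2 at 4.91. Plk1, a mitotic kinase, was at 7.47 (4.99 to 12.77).

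Lipid and stress lists differed less in these fibroblast-like cells. Sterol synthesis had 12 of 13 members higher and a median of 1.33 (1.00 to 1.57), with Sqle at 3.05. Fatty acid and triglyceride synthesis had 10 of 12 members higher and a median of 1.04, with Dgat1 at 2.35 and Elovl6 at 2.34. The list of fatty acid oxidation and lipid droplets had a median of -0.42 at percentile 0.01, with Pdk4 at -3.29 and Fabp4 at -2.26. Interferon response had 2 of 18 members higher and a median of -0.87 (-0.98 to -0.71), below all random lists, with Ifit3 at -2.78 and Irf7 at -2.59, and was -1.55 with free RNA subtracted. The immediate early and dissociation list had a median of -0.75, with Hspa1a at -3.39, Jun at -2.31 and Ier3 at 3.28. Oxidative stress response stood near other genes (median 0.33, percentile 39.6, and -0.072 under TMM factors), with Txnip at -4.68 and Srxn1 at 2.01. The lowest single genes were the acinar transcripts Tmed11 (at most -10.36, 0 UMIs in AP), Serpini2 (-10.62) and Klk1b11 (at most -9.42). They went along with acinar secretory RNA, which was 21.4% of the UMIs in NFD fibroblast-like cells and 0.0550% in AP.

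Macrophage-like cells of AP (1114) and NFD (285) differed in RNA of activation. They too lay in different clusters, 99.3% of those of NFD in 1, 88.8% of those of AP in another and 86.6% of those of HFD in yet another. In AP the inflammatory cytokine and chemokine list had 14 of 22 members higher, with a median of 1.03 (0.76 to 1.13) at percentile 99.97. Il6 was at 4.39 (2.84 to 6.67), the prostaglandin synthase Ptgs2 at 3.96 (3.55 to 4.39) and Cxcl3 at 3.49. Free RNA bears on this median, which was -0.054 after its subtraction, and clustering at resolution 0.5, which left 125 macrophage-like cells in AP, gave 0.29. The subtraction put free RNA at 15.1% of the macrophage-like RNA of AP. That would give more S100a9 than the 225 CPM counted in these cells, so the subtraction may take cell RNA too. The list of resident or alternatively activated macrophages had 1 of 12 members higher and a median of -2.31 (-2.44 to -2.17), below all random lists. Retnla, a mark of alternative activation, had 0 UMIs in AP and 300 in NFD (at most -10.04), Timd4 had 0 and 44 (at most -7.27), and the resident marker Lyve1 was at -5.95. Proliferation had all 14 members higher and a median of 3.41 (2.91 to 3.66), with Ccnb2 at 5.44 and Ube2c at least 5.34. MHC class II, which presents antigen, had a median of -0.58 (-0.76 to -0.37), with H2-Eb1 at -1.47 and Cd74 at -1.13, and its sign turned under other clusterings (0.99 at resolution 0.5).

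Other lists in macrophage-like cells of AP against NFD went both ways. Interferon response had a median of -0.63 with Ifit3 at -2.86, and immediate early genes had -0.80 with Hspa1a at -6.92 and Hspa1b at -6.18. With free RNA subtracted these medians were -1.67 and -1.51, that of MHC class II -1.41 and that of the resident list -3.44. Fatty acid oxidation and lipid droplets had -0.24 at percentile 0.26 (0.19 with CPM over all genes), with the fatty acid receptor Cd36 at -4.61. The lipid-associated macrophage list had a median of 0.25 at percentile 54.6 (-0.58 at resolution 0.5), with Spp1 at 4.80 and Gpnmb at 3.93 against Cd36. Fatty acid and triglyceride synthesis (1.20), sterol synthesis (0.70), oxidative stress (0.49) and inflammatory cell death (0.08, with Nlrp3 at 2.17) lay within the middle 95% of random lists. The collagen gene Col5a1 (at least 5.24) and the collagen chaperone Serpinh1 (6.48) were among the highest single genes. They stood beside a matrix list at 3.41 in these cells, and free RNA held 5895 CPM of Col3a1 in AP against 201 CPM in NFD. Tff2 (-9.15) and Tmed11 (at most -8.67) were among the lowest.

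Acinar-like barcodes were compared with 159 in AP and 10827 in NFD, and their RNA content differed in kind. Those of NFD had 0.176% mitochondrial RNA and 176 CPM of the nuclear RNA Malat1, against 0.630% and 828 CPM in AP. The acinar secretory list had 6 of 37 members higher in AP and a median of -0.53 (-0.54 to -0.35), below all random lists, while the median of all genes was 2.15. Rnase1 was at -1.89, the amylase Amy2a5 at -1.74 and Cela3a at -1.92. Amy2a1 had 0 UMIs in AP and 20 in NFD, which sets no direction at this depth. All 6 regenerating proteins were lower in AP, with a median of -2.55 (-2.59 to -2.48), Reg3a at -4.00 and Reg2 at -2.87. The acute-phase gene Lrg1 was at -5.03. The duct and metaplasia list had 13 of 14 members higher and a median of 4.08 (3.87 to 4.21), above all random lists, with the tight junction gene Cldn4 at 9.12, Cd44 at 6.93 and Anxa2 at 6.18. Some lists of other cell types were as high in the same barcodes, with medians of 5.82 for matrix and fibroblast activation, 5.12 for neutrophil activation, 4.85 for MHC class II, 4.79 for inflammatory genes and 4.48 for proliferation, while lipid-associated macrophage genes (2.26), resident macrophage genes (1.68) and endothelial activation (-0.70) were lower. S100a9 was 47.5 CPM in AP and 4.07 CPM in NFD. Whether the duct RNA came from acinar-like cells or from others was not tested. Oxidative stress response had a median of 2.34 with Srxn1 at 6.26 and Gclc at 5.53, and immediate early genes 2.16 with Nr4a1 at 4.54. The unfolded protein response had a median of 0.84 at percentile 0.78, with Trib3 at 3.77 and Ddit3 at 3.02, while fatty acid and triglyceride synthesis, at 1.94 with Me1 at 5.66, lay within the middle 95% (percentile 23.1). Kel (11.02, 8.50 to 16.34) and Npy (at least 9.07) were the other highest genes, and Tmed11 was at -4.49. Scaling weighed on all of these. Under TMM factors the medians were 1.94 for duct and metaplasia, 0.20 for oxidative stress, 0.022 for immediate early genes, -0.20 for fatty acid synthesis, -1.30 for the unfolded protein response and -2.67 for the secretory list. The secretory median was -0.064 with classes assigned cell by cell and -0.11 with free RNA subtracted.

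Neutrophil-like droplets were few in NFD (57) and held 49.2% acinar secretory RNA, against 0.426% in the 488 of AP. Interferon response had a median of -0.62 (0.33 with CPM over all genes) with Ifit3 at -2.47, and the neutrophil granule list -0.39 with the antimicrobial gene Camp at -2.30 and Mmp8 at 1.20. Neutrophil activation had 12 of 14 members higher and a median of 0.66 at percentile 62.7, with Siglecf at 3.45 and Cxcr4 at 3.18. The inflammatory list had 0.43, immediate early genes -0.34, oxidative stress 0.25 and inflammatory cell death 0.86, none beyond the middle 95% of random lists. Under TMM factors neutrophil activation (-0.22), the inflammatory list (-0.45) and inflammatory cell death (-0.023) turned sign, as did immediate early genes with CPM over all genes (0.60). The highest genes were the matrix genes Sparc (4.26) and Col5a1 (at least 3.27) and the gene Elmsan1 (at least 3.33). With free RNA subtracted no ratio was left for Sparc and Col5a1, and free RNA held 5895 CPM of Col3a1 in AP against 201 CPM in NFD. Whether this matrix RNA came from neutrophil-like cells was not tested. The lowest were Serpini2 (at most -8.34), Pdia2 (-8.63) and Tff2 (-7.94), the first 2 being acinar transcripts.

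HFD against NFD asks how the pancreas differed on the high-fat diet without pancreatitis. Immune-like cells were 28.4% of HFD cells (26.1 to 30.7) and 3.24% of NFD cells, a log2 ratio of 3.13 (2.87 to 3.39). Among cells that were not acinar-like the shares were 33.3% (30.7 to 35.9) and 28.7% (26.3 to 31.1), a log2 ratio of 0.22 (-0.02 to 0.45). The interval of this ratio is wider than a 95% interval, so it does not show whether counting error covers the difference. T-like and B-like cells made up more of the immune-like cells in HFD. T-like cells were 34.7% of them in HFD and 4.55% in NFD, and B-like cells 17.4% against 0 of 396 (95% interval up to 0.927%). NK-like cells went the other way, with 1.16% in HFD (5 cells) and 5.30% in NFD. ILC2-like cells had 0.926% (4 cells, 95% interval 0.253 to 2.35) and 2.53% (1.22 to 4.59), so their share intervals overlapped. Macrophage-like cells were 38.0% and 72.0%. Erythroid-like cells, 100 in all, came from HFD alone, where the haemoglobin gene Hbb-bs took 3.65% of all UMIs.

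The acute-phase genes Saa3, Lcn2 and Saa1 were far lower in fibroblast-like cells of HFD (666) than in those of NFD. They were named as the 3 lowest genes, and acute-phase genes had no list of their own. Saa3, a serum amyloid gene induced by inflammation, had 3 UMIs in HFD and 88091 in NFD, a log2 ratio of -15.45 (-17.73 to -13.90). Lcn2, an iron-binding defence protein, was at -7.40 (-7.74 to -7.08) and Saa1 at -7.50 (-9.13 to -6.27). Interferon response had 4 of 18 members higher and a median of -1.30 (-1.47 to -0.95), below all random lists, with Irf7 at -3.36 and Ifit3b at -2.99. The matrix and activation list had 4 of 16 higher and a median with an interval of -1.11 to -0.87, with the protease inhibitor Timp1 at -5.97 and Col3a1 at -2.53. The inflammatory list had a median of -0.19 at percentile 1.76 (0.12 with CPM over all genes), with Ccl7 at -2.08, Il6 at -1.22 and Ptgs2 at 1.04. Proliferation (-0.03), immediate early genes (0.12, and -0.19 under TMM factors), oxidative stress (0.07), fatty acid synthesis (0.36), sterol synthesis (0.59) and fatty acid oxidation (-0.06) lay within the middle 95% of random lists. In them Ier3 was at 2.24, Hmox1 at -2.18, Scd1 at 1.12 and Cd36 at 3.48. Car3 (at least 7.58), Cyp2e1 (at least 5.41) and Pck1 (at least 4.99), genes high in fat and liver, had 0 UMIs in NFD, but with classes drawn at resolution 2 only 4, 3 and 1 of their UMIs were left in this class in HFD, too few for a ratio, and Cd36 had 4 in HFD and 3 in NFD. Acinar secretory RNA was 1.78% of UMIs in these cells in HFD and 21.4% in NFD.

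Macrophage-like cells of HFD (164) had more RNA of the resident or alternatively activated state than the 285 of NFD. That list had 11 of 12 members higher and a median of 2.01 (1.87 to 2.23), above all random lists, with Retnla at 4.79 (4.63 to 4.96), Clec10a at 4.62 and Mgl2 at 3.71. Its exception was Arg1, with 0 UMIs in HFD and 363 in NFD (at most -7.19). All 7 measured MHC class II genes were higher, with a median of 1.21 (1.12 to 1.29), Ciita at 1.84 and H2-Aa at 1.64. The inflammatory list had 6 of 17 higher and a median of -0.58 (-0.85 to -0.17), below all random lists, with Il1b at -2.61, Osm at -1.37 and Il10 at 1.66. Proliferation had a median of -1.55 with Top2a at -2.21, and the lipid-associated list had -0.43 with Spp1 at -4.44, Fabp5 at -4.08 and Apoe at 1.72. Immediate early genes had 0.67 at percentile 99.7 with Socs3 at 1.65. Interferon response (0.58, and -0.28 with free RNA subtracted), sterol synthesis (0.81), fatty acid synthesis (-0.23), fatty acid oxidation (0.19, and -0.17 with free RNA subtracted), oxidative stress (-0.21) and inflammatory cell death (0.41) lay within the middle 95%, with Ifit3b at 2.39 and Ninj1 at 2.26 among their members. Prg4 (at least 6.93) and the lipoxygenase Alox15 (at least 5.38), genes of peritoneal and resident macrophages, were highest, and the histone gene Hist1h2ap (-7.86) and the chemokine Ccl5 (-5.92) were lowest.

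Acinar-like cells of HFD (225) differed most from the NFD barcodes in the regenerating proteins, which pancreas injury induces. All 6 were lower, with a median of -6.33 (-6.42 to -6.24), Reg3g at -9.59 (-10.43 to -8.87), Reg3a at -8.83 and Reg3b at -8.24. The acinar secretory list had 26 of 37 higher and a median of 0.46 (0.44 to 0.61), above all random lists, led by the amylases Amy2a3 at 3.62 and Amy2a5 at 3.35, with Prss1 at -4.08. Duct and metaplasia genes had 3 of 12 higher and a median of -0.95 with Krt8 at -1.55. Immediate early genes had -0.84 with Hspb1 at -2.82, and fatty acid synthesis -0.49 at percentile 2.06. The unfolded protein response (0.17, with Chac1 at -3.39 and Pdia4 at 1.91) and oxidative stress (-0.39, and 0.26 at resolution 2) lay within the middle 95%. Ly6d was at 8.61 on 36 and 2 UMIs. Malat1 was 489 CPM in these cells and 176 CPM in the NFD barcodes.

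**Figure D3:**
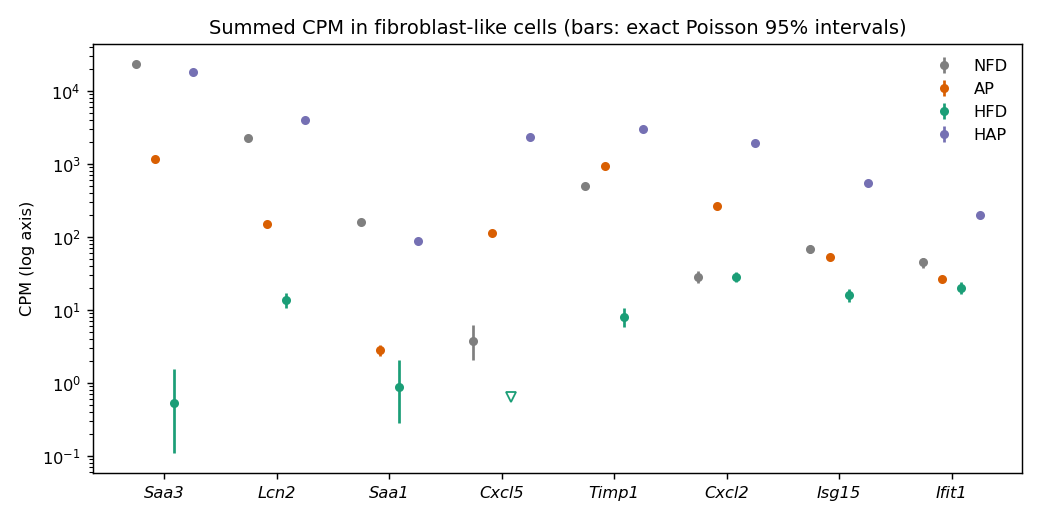
Summed CPM (log axis) of 8 genes in fibroblast-like cells of the 4 libraries, with exact Poisson 95% intervals as bars and a triangle where no UMI was counted. Saa3 was 23302 CPM in NFD, 1156 in AP, 0.521 in HFD and 18026 in HAP, and Isg15 was highest in HAP at 546 CPM. For Cxcl2 in HAP, free RNA scaled by acinar secretory RNA would give the level shown. The same scaling would give more S100a9 than the 1771 CPM counted in these cells, so it overstates free RNA there.

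HAP against HFD asks how the pancreas differed with pancreatitis on the high-fat diet. Most kept cells of HAP were neutrophil-like. They were 68.7% of HAP cells (67.3 to 70.0) and 1.97% of HFD cells (1.33 to 2.80), a log2 ratio of 5.12 (4.59 to 5.71). Immune-like cells as a whole were 71.0% and 28.4%, a log2 ratio of 1.32 (1.18 to 1.47), and among cells that were not acinar-like the ratio was 1.09 (0.96 to 1.24). Within the immune-like cells of HAP, 96.7% were neutrophil-like, 2.51% monocyte-like (81 cells) and 0.0931% macrophage-like (3 cells). T-like cells numbered 150 in HFD and 1 in HAP. Acinar-like cells were 14.8% in HFD and 0.0441% in HAP (2 cells). The macrophage and acinar lists therefore have no value in HAP, and fibroblast-like cells alone could be compared. How many HAP cells were called neutrophil-like depended on clustering, with 46.5% at resolution 2, where 23.9% were called monocyte-like.

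Fibroblast-like cells of HAP (864) had higher inflammatory and interferon lists than those of HFD (666), together with more RNA of the acute-phase gene Saa3. The inflammatory list had 20 of 21 members higher and a median of 3.50 (3.26 to 3.73), above all random lists, with Cxcl5 at least 12.11 (31882 UMIs against 0), Ccl3 at 9.55 (7.70 to 12.60) and Cxcl3 at 8.97 (7.42 to 11.25). Free RNA subtraction gave a median of 2.44 and left Ccl3 with 0 UMIs in both libraries. Neutrophil RNA was present in these droplets, with S100a9 at 1771 CPM in HAP and 320 CPM in HFD. Cxcl5 was 2299 CPM in HAP fibroblast-like cells and 95.6 CPM in the neutrophil-like cells of that library, whereas Ccl3 was 261 and 9681 CPM. Interferon response, the antiviral programme, had 17 of 18 members higher and a median of 2.46 (2.36 to 2.67), above all random lists, with Isg15 at 5.13 (4.83 to 5.44), Irf7 at 3.88 and Ifi44 at 3.72. With free RNA subtracted its median was 2.59. The matrix and activation list had 11 of 18 higher and a median of 1.25 (0.53 to 1.28), with Saa3 at 15.08 (13.53 to 17.36), Timp1 at 8.56 (8.14 to 9.01) and Tnc at least 7.18. Oxidative stress response had 11 of 15 higher and a median of 1.01 (0.88 to 1.24), with the cystine transporter Slc7a11 at 5.18, Sod2 at 3.84 and Txnip at -4.18. Proliferation had 12 of 14 higher and a median of 1.49, with Mcm5 at 5.23 and Tyms at 2.31.

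Immediate early genes were lower in HAP fibroblast-like cells, with a median of -1.27 (-1.33 to -1.21), Atf3 at -4.53 and Fos at -2.87. Sterol synthesis (0.82), fatty acid and triglyceride synthesis (0.37) and fatty acid oxidation (-0.16) lay within the middle 95% of random lists, with Lss at 1.92, Dgat2 at 2.88 and Fabp5 at 2.73. The lowest single genes were Car3 (at most -9.46), the methyltransferase Inmt (-9.75, -10.53 to -9.07) and Fam71a (at most -7.72). The HAP cluster behind these values had 4 of 8 fibroblast markers raised over the other clusters, and with a minimum of 6000 UMIs its 667 HAP cells could not be named.

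**Figure D4:**
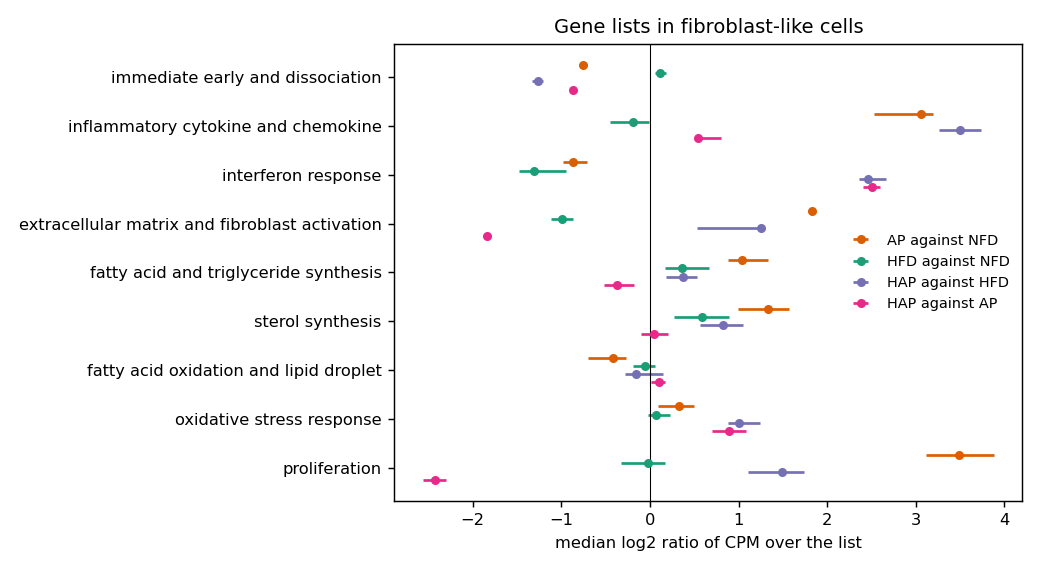
Median log2 ratio of CPM over 9 gene lists in fibroblast-like cells for the 4 comparisons, with 95% counting intervals as bars. The interferon response list lies at 2.46 and 2.50 for HAP against HFD and against AP, and at -0.87 and -1.30 for AP and HFD against NFD.

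HAP against AP asks how pancreatitis differed between diets. Neutrophil-like cells were 68.7% of HAP cells and 8.85% of AP cells, a log2 ratio of 2.96 (2.81 to 3.11). Immune-like cells were 71.0% and 49.5%, a log2 ratio of 0.52 (0.45 to 0.59). Macrophage-like cells were 20.2% of AP cells (1114) and 0.0662% of HAP cells, dendritic-like cells 11.3% (625) and 0.176%, and NK-like cells 3.63% (200) and 0.0221%. The split of macrophage-like from monocyte-like cells depended on clustering. At resolution 0.5 AP had 125 macrophage-like and 1224 monocyte-like cells, and HAP had 81 monocyte-like cells as reported and 1084 at resolution 2. Ductal-like cells were 7.23% of HAP (328) and 0.417% of AP (23), and fibroblast-like cells 19.1% and 39.5%. With a minimum of 1000 UMIs in AP, HFD and HAP, neutrophil-like cells, which hold little RNA, were 76.6% of HAP and 24.5% of AP, and with a minimum of 6000 UMIs 48.1% and 0.379%, so the size of this difference depended on the minimum.

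Interferon response was higher in HAP in fibroblast-like and neutrophil-like cells. In fibroblast-like cells (864 and 2178) it had 17 of 18 members higher and a median of 2.50 (2.40 to 2.60), with Ifit3 at 3.67 (3.53 to 3.82), Isg15 at 3.36 (3.29 to 3.42) and Usp18 at 3.34. Ifi206, an interferon-induced gene, was the highest single gene there at 6.43 (5.97 to 6.92). Neutrophil-like cells (3115 and 488) had 16 of 17 members higher and a median of 3.24 (2.95 to 3.45), above all random lists, with Usp18 at 4.41, Ifit3 at 4.07 and the nucleic acid sensor Zbp1 at 3.92. The median of all genes in neutrophil-like cells was -1.15.

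Matrix and division genes were lower in HAP than in AP fibroblast-like cells. The matrix and activation list had 3 of 18 higher and a median of -1.84 (-1.89 to -1.81), below all random lists, with Acta2 at -7.04 (-7.79 to -6.37), Tagln at -3.76 and Tgfb1 at -3.48, against Saa3 at 3.96. Proliferation had 4 of 14 higher and a median of -2.43 (-2.56 to -2.31), with Ccnb2 at -5.59 and Ube2c at -5.37. H19 (-7.64), the growth factor Ptn (-6.59) and the collagen-binding Fmod (at most -5.98) were lowest. Oxidative stress response had 11 of 15 higher and a median of 0.90 (0.70 to 1.09), with Slc7a11 at 4.37, Sod2 at 3.84 and the haem oxygenase Hmox1 at 2.98. The metallothionein Mt4 was at 6.26 and Olfr90 at least 6.18. The inflammatory list had 15 of 22 higher and a median of 0.54 (0.52 to 0.81), with Ccl3 at 5.48, Cxcl3 at 4.55 and Cxcl5 at 4.34. Its sign turned under 6 alternatives, among them free RNA subtraction at -0.92, which left Ccl3 with 0 UMIs in both libraries. Immediate early genes had -0.87 with Atf3 at -3.23. Sterol synthesis (0.04), fatty acid synthesis (-0.37) and fatty acid oxidation (0.10) lay within the middle 95%, with Lss at 1.09, Dgat2 at 2.83 and Fabp4 at 4.07.

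Summed over clusters, neutrophil-like cells of HAP carried more granule and chemokine RNA than those of AP. In HAP, 1846 of them lay in a cluster with Ccl3 and Cxcl3 among its leading genes. Another 1269 lay in a cluster led by the granule genes Ngp and Camp. Of those of AP, 98.6% lay in yet another cluster. The sums merge these clusters, so state, subset and library were not told apart. The granule list had 6 of 8 higher and a median of 1.37 (1.23 to 1.58), with Lcn2 at 5.01 (4.93 to 5.09), Camp at 3.78 and Ngp at 3.40. Scaled by the acinar secretory RNA in them, free RNA was put at 37.8% of the RNA of these cells in HAP and 90.9% in AP. Among barcodes with at least 100 UMIs the fullest bin was 250 to 500 UMIs in both libraries, far below these cells. The scaling therefore appears to overstate free RNA here. The free RNA of HAP held 40503 CPM of S100a8. With free RNA subtracted at this scaling, which may take cell RNA too, the granule median was 0.52 and that of neutrophil activation 0.15. The inflammatory list had 14 of 22 higher and a median of 0.98, above all random lists, with Ccl3 at 5.38 (5.24 to 5.52), Ccl4 at 3.51 and Il6 at -3.04. Neutrophil activation had 10 of 14 higher and a median of 0.51 at percentile 99.6, with the formyl peptide receptor Fpr1 at 2.77, Cd274 at 2.58, Cxcr4 at -2.77 and Siglecf at -7.21 (-7.82 to -6.66). Immediate early genes had 0.47 with Jun at 3.04, inflammatory cell death 0.04 at percentile 99.9 with Casp1 at 1.95 and Casp4 at 1.81, and oxidative stress -0.39 at percentile 89.6 (0.76 under TMM factors) with Sod2 at 2.96. Orm1 (8.71, 6.86 to 11.76) and Lipg (7.07) were the other highest genes, and Nr4a2 (-8.41) and Pld4 (-9.00) the lowest beside Siglecf. These cells held 5854 UMIs on average in HAP and 3810 in AP, and at a minimum of 6000 UMIs AP kept only 16 of them.

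Mesothelial-like cells, the lining of the organ, numbered 55 in HAP and 411 in AP. Of those of HAP 98.2% lay in a single cluster and of those of AP 99.8% in another, so state, subtype and library were not told apart. All 14 proliferation genes were lower in HAP, with a median of -3.74 (-4.15 to -3.28), Mki67 at -6.39 (-7.84 to -5.27), Ccnb2 at most -5.69 and the histone gene Hist1h2ap at -8.69. Immediate early genes had a median of -0.67 with Nr4a1 at -3.46. Ivl (at least 7.43), the acute-phase gene Orm1 (at least 6.08) and Wfdc21 (6.07) were highest, and S100a9, a neutrophil RNA, was 1989 CPM in HAP and 115 CPM in AP.

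The pancreatitis ratio of the immune share was smaller on the high-fat diet over all cells, with a difference in log2 of -2.61 (-2.93 to -2.28). Among cells that were not acinar-like the difference was 0.26 (-0.04 to 0.56), so the sign depended on whether acinar-like cells were counted. The T and NK effector list and the endothelial activation list had no class of their own with 50 cells in both libraries. In fibroblast-like cells their medians for AP against NFD were 0.52 and -0.72, and the endothelial list, which holds Lcn2, Cxcl1 and Lrg1, had 2.30 for HAP against HFD. Genes that recur above lie as follows on mm10. Saa3 (ENSMUSG00000040026) is on chromosome 7 from 46711998 to 46715700, Cxcl5 (ENSMUSG00000029371) on chromosome 5 from 90759360 to 90761624, and Timp1 (ENSMUSG00000001131) on chromosome X from 20870166 to 20874735. Isg15 (ENSMUSG00000035692) is on chromosome 4 from 156199424 to 156200818, Ccl3 (ENSMUSG00000000982) on chromosome 11 from 83647844 to 83649355, Retnla (ENSMUSG00000061100) on chromosome 16 from 48842551 to 48844461, and Reg3b (ENSMUSG00000071356) on chromosome 6 from 78370657 to 78373466.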

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

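The test of scaling was chosen only after the result was seen, and the test of neutrophil RNA before it. The 4 pairs of values below were singled out because pancreatitis went with opposite directions on the normal and the high-fat diet. With 1 library per group none of these differences between diets was tested.

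The interferon response list in fibroblast-like cells was at -0.87 for AP against NFD and 2.46 for HAP against HFD. RNA of neutrophils in the fibroblast-like droplets of HAP was weighed first, because interferon genes were also high in neutrophil-like cells. Scaled by S100a9, that RNA would give 2.81% of the CPM of the median list member, which argues against it. For HAP against HFD, scaling over unlike RNA contents is argued against too, since TMM factors left 93.1% of the list median (2.29 against 2.46). These factors shift every gene alike, here by 0.17. What stays open is the diet together with pancreatitis, a response in the animals behind this 1 library, and handling of the tissue, which the groups do not separate and which may each account for the pattern. Both tests bear on HAP only. The negative value rests on NFD as the control, and the list was lower in HFD than in NFD too (-1.30). Isg15 in these cells was 68.5 CPM in NFD, 53.3 in AP and 15.6 in HFD. An unusual NFD library stays open for the negative value and was not tested.

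The ductal-like share of cells that were not acinar-like had a log2 ratio of -3.10 for AP against NFD and 2.16 for HAP against HFD. All ductal-like cells of NFD and HFD lay in a single cluster, and all those of AP and HAP in another. The latter had 9 of 9 ductal markers raised but 0 among its leading genes. Each ratio thus compares cells of different clusters, and whether they are the same cell type was not tested. For the mesothelial-like share the ratios were 2.64 and -1.02. Of these cells 99.8% of those of AP lay in a single cluster and 100% of those of NFD in another, so the first ratio compares different clusters too. For the NK-like share the ratios were 1.30 and -4.13, the last on 1 cell in HAP and 5 in HFD. NK-like cells of NFD (100%) and AP (99%) also lay in different clusters.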

How the results depend on the processing

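Alternatives fixed before the data were examined existed only for the immune share ratios and for the inflammatory list in macrophage-like and the acinar secretory list in acinar-like cells. For these results, those chosen only afterwards were the minimum of 10000 UMIs in NFD, that of 1000 UMIs in the other libraries, automatic doublet calls, CPM without rRNA-like genes, free RNA of barcodes with 250 to 2000 UMIs, free RNA subtraction from the acinar secretory list, and leaving acinar-like cells out. For all other lists and for single genes every alternative was chosen afterwards. A value counted as moved when it left the counting interval of the reported value. Of the immune share ratios under alternatives, 36 stayed within it, 18 moved and 1 turned sign. Of the medians of those lists, 4 in number, 36 values stayed, 19 moved and 1 turned sign. Among 86 other list medians 873 values stayed, 227 moved and 34 turned, and among 401 single genes 4280 stayed, 784 moved and 16 turned. For single genes 71 further values had under 20 UMIs and 9 were bounds that set no direction. They are not counted, a rule applied to the alternatives after their values had been seen. It left out sign changes of Car3, Cyp2e1, Pck1 and Cd36 in fibroblast-like cells of HFD against NFD. The cause of these shifts was not tested.

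The immune share ratio for AP against NFD (3.93) became 3.16 with 2 times the UMI minimum, 4.26 with 10000 UMIs in NFD, 4.20 with 1000 UMIs in the others, 3.63 with cells thinned to 500 UMIs and 0.83 without acinar-like cells. For HFD against NFD (3.13) it was 2.41, 3.47 and 0.22 under the first, the second and the last of these. For HAP against HFD (1.32) it was 1.15 with 2 times the UMI minimum, 1.58 with 1000 UMIs in the others and 1.09 without acinar-like cells. For HAP against AP (0.52) it was 0.39 with 2 times the UMI minimum, 0.68 at resolution 2, 0.43 with 1000 UMIs in the others and 0.95 when thinned. The difference between diets (-2.61) was -2.02 with 2 times the UMI minimum, -2.95 with 10000 UMIs in NFD, -2.24 when thinned and 0.26 without acinar-like cells.

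The inflammatory list in macrophage-like cells for AP against NFD (1.03) was 0.60 with 2 times the UMI minimum, 0.29 at resolution 0.5, 1.46 with CPM over all genes, 0.57 with TMM, -0.054 with free RNA subtracted and 0.12 with free RNA of barcodes with 250 to 2000 UMIs. For HFD against NFD (-0.58) it was -0.88 with TMM, -1.08 with free RNA subtracted and -0.89 with the other free RNA profile. The acinar secretory list for AP against NFD (-0.53) was -0.64 with 2 times the UMI minimum, -0.55 at resolution 2, -0.064 with classes cell by cell, -0.69 with 10000 UMIs in NFD, -2.67 with TMM and -0.11 with free RNA subtracted. For HFD against NFD (0.46) it was 0.40 with 2 times the UMI minimum, 0.61 cell by cell, 0.29 with 10000 UMIs in NFD, 0.42 with TMM and 0.36 without rRNA-like genes.

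Other lists that turned sign for AP against NFD in macrophage-like cells were MHC class II (0.99 at resolution 0.5, 0.48 cell by cell), the lipid-associated list (-0.0080 with 2 times the UMI minimum, -0.58 at resolution 0.5, -0.21 with TMM, -0.19 with free RNA subtracted) and fatty acid oxidation (0.19, CPM over all genes). In acinar-like cells they were the unfolded protein response (-1.30 with TMM, -3.84 with free RNA subtracted) and fatty acid synthesis (-0.20 and -1.71 under the same). In neutrophil-like cells the inflammatory list (-0.45 and -0.79) and inflammatory cell death (-0.023 and -0.32) turned under the same, neutrophil activation with TMM (-0.22), and immediate early genes (0.60) and interferon response (0.33) with CPM over all genes. Oxidative stress in fibroblast-like cells turned with TMM (-0.072). By the scaling used, free RNA took 100% of the acinar-like RNA in both libraries, and 90.9% of the neutrophil-like RNA in AP and 100% in NFD, so its subtraction there removes cell RNA too or leaves little.

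For HFD against NFD, lists that turned in fibroblast-like cells were the inflammatory list with CPM over all genes (0.12) and immediate early genes with TMM (-0.19) and free RNA subtracted (-0.069). In macrophage-like cells they were fatty acid oxidation under the same (-0.11 and -0.17) and interferon response with free RNA subtracted (-0.28), and in acinar-like cells oxidative stress at resolution 2 (0.26). For HAP against AP the inflammatory list in fibroblast-like cells was -0.22 with doublets kept, -0.11 at resolution 2, -0.079 with 10000 UMIs in NFD, -0.019 with 1000 UMIs in the others, -0.12 with automatic doublet calls and -0.92 with free RNA subtracted. Oxidative stress in neutrophil-like cells was 0.76 with TMM and 0.37 with free RNA subtracted.

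Single genes that turned in HFD against NFD were Mki67 (-0.55, 10000 UMIs in NFD) and Hspa1b (at least 6.03 with free RNA subtracted, which left 0 UMIs in NFD) in fibroblast-like cells, Spp1 (1.66, 10000 UMIs in NFD) and Nfe2l2 (0.38 at resolution 2) in acinar-like cells, and Hspb1 in macrophage-like cells (0.16, free RNA subtracted). In AP against NFD they were H2-Ab1 (0.99 at resolution 0.5, 0.024 cell by cell), H2-Eb1 (0.37) and Cd74 (0.57) at resolution 0.5 in macrophage-like cells, Pdia4 (-0.24) and Xbp1 (-0.020) with TMM and Scd2 (-0.066) cell by cell in acinar-like cells, and Mmp8 in neutrophil-like cells (-0.068, 1000 UMIs in the others). In HAP against HFD it was Cd36 in fibroblast-like cells (1.37 at resolution 2), and in HAP against AP Acsl4 in neutrophil-like cells (0.28, TMM) and Cxcl2 in fibroblast-like cells (at most -9.02 with free RNA subtracted, which left 0 UMIs in HAP).

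Some settings left under 50 cells and gave no value. They were macrophage-like and neutrophil-like lists with 10000 UMIs in NFD (24 and 0 cells), neutrophil-like lists with 2 times the UMI minimum (16 cells in AP), those of AP against NFD with classes cell by cell (36 cells in NFD), and the fibroblast-like lists of HAP with 2 times the UMI minimum (1 cell). Depth limits single genes near 20 UMIs, and no setting replaces the missing replicates.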

Other observations

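The test of free RNA for the acute-phase genes was chosen only after the result was seen, and the other tests of this part before it. That Malat1 of deep barcodes also had to pass was decided afterwards. Macrophage-like cells of AP and HFD lay at opposite ends of several lists relative to NFD. Retnla was 238 CPM in NFD, 6602 CPM in HFD and had 0 UMIs in AP, while Il1b was 300 CPM in NFD, 49.3 CPM in HFD and 1437 CPM in AP. In mesothelial-like cells of HAP against AP the interferon response list had 11 of 17 members higher and a median of 1.05 (0.80 to 1.22), above all random lists, beside a neutrophil granule list at 4.83.

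Acinar-like barcodes made up 88.7% of the kept NFD barcodes. A candidate explanation is droplets that hold free acinar RNA and no cell. If so, Malat1, a nuclear RNA, would be as low in them as in NFD barcodes with 1000 to 2000 UMIs, and it was 1.25 times that level (176 against 141 CPM). A minimum of UMIs below the depth of empty NFD barcodes stays open too. At a minimum of 10000 UMIs 86.9% stayed acinar-like, but this would count against it only if deep barcodes held cells. Acinar-like barcodes with 10000 to 20000 UMIs and with over 20000 held 142 and 117 CPM of Malat1, no clear gain over the level of 141. Lysed acinar cells in this 1 preparation and a tissue truly rich in acinar cells also stay open.

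Saa3, Lcn2 and Saa1 were far higher in NFD than in HFD fibroblast-like cells, although NFD was taken as the untreated control. Free RNA with the profile of NFD barcodes with 10 to 100 UMIs is argued against, since the median of the 3 genes was 16.2 times their level there. These barcodes held 0.199% of the UMIs of NFD. Whether they stand for the free RNA in its fuller droplets was not tested. If the NFD and AP labels were exchanged, the library titled AP would be untreated and was predicted to be near HFD. The ratio of AP to HFD was a median of 11.1 over the 3 genes and 3.19 at the lowest. It cannot decide the question, because these genes were chosen as the lowest in HFD against NFD. The ratio also crosses the diets. An exchange of these labels therefore stays open. Within the normal diet immune-like cells were 51.0% of cells that were not acinar-like in AP and 28.7% in NFD, the order of the labels. The 3 genes have the other order, with 23302 CPM in NFD against 1156 in AP for Saa3, 2260 against 148 for Lcn2 and 157 against 2.77 for Saa1. They do not stand alone. Lrg1 was 223 against 9.80 CPM in fibroblast-like cells, and all 6 regenerating proteins were lower in AP acinar-like cells (median log2 ratio -2.55). In fibroblast-like cells the interferon list was lower in AP (-0.87) and the inflammatory list higher (3.06), so measures within the normal diet were split. A wrong label of the NFD library alone, an injury or infection in the animals behind it, and the diet, which the design names, stay open as well and were not tested.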
